A study of Mus musculus with 11 samples.

How the data were processed

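The series holds 11 Affymetrix Mouse Gene 2.0 ST arrays of sorted bone marrow CLPs from C57BL/6 mice. Per the labels, 5 ng of RNA was amplified with the NuGen SPIA method and 5 µg of cDNA was labelled. The deposited values are on the log2 scale, and the authors made them with RMA in Partek, per the submitters' processing notes; the versions and further settings are not given in the sources used here. RMA corrects background, normalises quantiles across arrays and summarises probes by median polish. The quartiles of the arrays were nearly equal, and detection values were not used here, so the number of arrays per group, 2 or 3, sets the precision. Samples were grouped by the population and treatment in their titles.

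The table held 41345 probe sets, 25335 of them with genes in the supplied probe table. Only the 23521 with exactly 1 gene symbol were used, and each of 22180 genes was represented by its probe set with the highest mean over all arrays, a choice to make for 1082 genes. The 17824 probe sets without a single symbol were tested apart from the comparisons. Rag1, Cd74 and Hba-a1 share their probe sets with other symbols, and these and further list members without a probe set of their own were not analysed here. Symbols are those of the probe table.

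All comparisons came from 1 linear model with a mean for each of the 4 groups, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 7 residual and 3.48 prior degrees of freedom). The contrasts were CpG minus PBS in Ly-6D+ CLPs and in Ly-6D- CLPs, their average and their difference, and Ly-6D+ minus Ly-6D- CLPs after PBS and after CpG. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over 22180 genes. SE is the standard error of a log2 change from the spread moderated by eBayes, and means are given with the SD between arrays. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

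Comparisons, alternatives, lists and the rule for named genes were written before the data were examined, except where an alternative is said to have been added. The rule took, among genes that passed and whose arrays did not overlap between groups, the 12 largest rises and 12 largest falls for the CpG effect in each population and for the populations after PBS, and 6 and 6 for the others. Overlap was not considered for the average and the difference. With fewer than 5 genes passing, the 10 smallest p values were named as not having passed. Predicted and numbered symbols (Gm, Rik, Mir, Snor, n-R5, LOC) were passed over. Up to 4 members of each list with the smallest p, and Ly6d, Tlr9, Il7r, Flt3, Kit, Ly6a, Ebf1, Pax5, Rag1 and Irf7, were added, and names were left out for readability.

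The 21 lists were interferon-stimulated genes, interferon-gamma-inducible GTPases and chemokines, MHC class I antigen presentation, MHC class II antigen presentation, Toll-like receptor signalling components, NF-kB targets, B-lineage specification, early lymphoid progenitor genes, T-cell markers, NK and innate lymphoid markers, plasmacytoid dendritic cell markers, conventional dendritic cell markers, granulocyte and monocyte markers, erythroid and megakaryocyte markers, haematopoietic stem cell markers, mature B-cell and plasma-cell markers, G1/S cell cycle genes, G2/M cell cycle genes, apoptosis regulators, cytokine receptors, and immediate-early and heat-shock genes. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move one way without comparing them with other genes. An exact permutation of the list means per array, with treatment permuted within population (200 arrangements), was added after the data were seen.

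Alternatives were every probe set by itself, the mean of a gene's probe sets, the dimmest 33.3% of genes left out, eBayes with a variance trend and robust estimation, array weights, only the groups compared, a further quantile normalisation, centring of each array on its median, an adjusted p below 0.10, a minimum of 1.5-fold, the replicate number as a block, that number within treatment as a block, and leaving out each array in turn. Leaving out 1 Ly-6D+ PBS array leaves a single array in that group, which is then assumed to vary like the other groups. A fit without the arrays numbered 3 was added after the data were seen. Other splits of the arrays were counted for CpG in Ly-6D- CLPs, the average, and the populations after CpG. The average includes the Ly-6D+ PBS group of 2 arrays. The fit took all arrays as independent, but the labels do not say whether the 2 populations share animals.

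The fit was tested on simulated data with the layout of these arrays and 200 changed genes in each comparison. At 2-fold, 73.1% of changed genes were recovered for CpG in Ly-6D+ CLPs, 70.1% in Ly-6D- CLPs, 98.5% for the average, 43.3% for the difference, and 68.7% and 79.1% for the populations after PBS and CpG. At 1.5-fold the shares were 35.8%, 29.9%, 59.7%, 11.9%, 26.9% and 34.3%. False calls made up 2.27% to 11.0% of all calls, and 0 calls had the wrong sign. The simulated noise was independent between genes and between arrays. The adjusted threshold is easier to reach when more genes change. For CpG in Ly-6D+ CLPs the simulation called 146 genes, against 6 in the data, so these shares may overstate the recovery.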

Results

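Gene expression was measured on 11 microarrays in common lymphoid progenitors (CLPs), the bone marrow cells that give rise to lymphocytes. C57BL/6 mice had received PBS or 50 µg of CpG1826, a synthetic oligonucleotide ligand of Toll-like receptor 9, and the CLPs were sorted on day 10 by their surface Ly-6D, a marker that appears on CLPs as they enter the B lineage. There were 3 arrays of Ly-6D+ CLPs from CpG-treated mice, 2 of Ly-6D+ CLPs from PBS-treated mice, 3 of Ly-6D- CLPs from CpG-treated mice and 3 of Ly-6D- CLPs from PBS-treated mice. The labels do not say whether replicates were separate animals or pools, so each p measures only the spread between these samples. The number of arrays limits the precision, and detection values were not used here, so signal over background is unknown. The array medians lay between 3.85 and 3.96 on the log2 scale. The correlation between arrays, taken across all 41345 probe sets, which are not independent replicates, was 0.978 to 0.982 within groups and 0.973 to 0.981 between groups. On the first principal component, with 27.3% of the variance, the Ly-6D+ arrays lay between -25.6 and -16.3 and the Ly-6D- arrays on the other side of it, at 13.4 or more.

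Ly6d, the gene of the sorted surface protein, was used to check the population labels. Its level was 12.58 ± 0.02 (SD, n = 2) in Ly-6D+ CLPs after PBS and 12.57 ± 0.03 (SD, n = 3) after CpG, against 8.23 ± 0.24 and 7.72 ± 0.32 (SD, n = 3 each) in Ly-6D- CLPs. No array of one population reached the range of the other. CpG moved Ly6d by less than the spread between arrays in Ly-6D+ CLPs (log2 change -0.00, SE 0.18, limma adjusted p of 1) and by -0.50 in Ly-6D- CLPs (SE 0.16, adjusted p = 0.225), which did not pass.

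The first question was what CpG changed in Ly-6D+ CLPs, the population already entering the B lineage. The genes of MHC class II, the molecules that present peptides to helper T cells, rose. H2-Eb1 went from 5.73 ± 0.04 (SD, n = 2) to 9.02 ± 0.42 (SD, n = 3), a rise of 9.77-fold (SE 0.25 on the log2 scale, limma adjusted p = 9.26e-04). H2-Aa rose 9.21-fold (SE 0.21, adjusted p = 3.80e-04) and H2-Ab1 rose 3.99-fold (SE 0.20, adjusted p = 0.00563). Ehd3, of the EHD family of membrane-trafficking proteins, rose 5.11-fold (SE 0.30, adjusted p = 0.0349) and Muc13, a transmembrane mucin, rose 2.11-fold (SE 0.13, adjusted p = 0.0318). Gm4951, outside the rule for named genes and chosen after its values were seen, had a log2 change of 3.14 (SE 0.29, adjusted p = 0.00390). These were all 6 genes that passed, and 0 genes fell by the default limma test, against 13 higher and 5 lower with a variance trend and robust estimation. Of all 22180 genes, 1443 had an unadjusted p under 0.05, 694 higher and 749 lower.

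Of the 9 measured members of the MHC class II list, 3 rose over all genes tested and 6 when adjusted over the list alone, and the list rose (median log2 change 1.10, camera adjusted p = 1.56e-16, adjusted p = 0.0318 with an estimated correlation). Ciita, the transactivator of these genes, had a log2 change of 1.10 (SE 0.21) and did not pass (adjusted p = 0.179). All 15 measured interferon-gamma-inducible GTPases and chemokines were higher, 0 of them past the test over all genes and 11 when adjusted over the list alone. That list rose too (median 0.74, camera adjusted p = 6.35e-17, adjusted p = 0.0380 with an estimated correlation), with log2 changes of 2.68 for Iigp1 (SE 0.39, adjusted p = 0.0931), 0.96 for Gbp7 and 0.95 for Igtp. The B-lineage specification list fell (median -0.21, camera adjusted p = 2.95e-09, adjusted p = 0.0318 with an estimated correlation), with 20 of 23 measured members lower, 0 of them past the test over all genes and 4 when adjusted over the list alone. Among them were Pou2af1, a B-cell transcriptional coactivator (-1.89, SE 0.33, adjusted p = 0.120), and Vpreb3 (-1.35, SE 0.21, adjusted p = 0.117). MHC class I antigen presentation passed upward by camera (median 0.24, 0 of 15 past over all genes and 2 when adjusted over the list alone, camera adjusted p = 4.81e-05), a call lost at adjusted p = 0.356 with an estimated correlation. The cytokine receptor list (median 0.10) and the G2/M list (median -0.10) each had a camera adjusted p of 0.0451, lost at adjusted p = 0.572 and 0.621 with an estimated correlation. The fry adjusted p was 0.0850 for MHC class I, 0.283 for the cytokine receptor list and 0.457 for the G2/M list. In these 2 lists 0 members passed over all genes, and 2 and 0 when adjusted over the list alone. Both calls ended without Ly-6D+ CpG replicate 1 or 2, Ly-6D+ PBS replicate 1, Ly-6D- CpG replicate 2 or Ly-6D- PBS replicate 2. The G2/M call ended also without Ly-6D+ PBS replicate 2 or Ly-6D- CpG replicate 1 and the cytokine receptor call without Ly-6D- PBS replicate 3, with adjusted p up to 0.228 and 0.370. Medians moved by more than 1.5 times for B-lineage specification without Ly-6D+ CpG replicate 3 (-0.39), for G2/M genes without Ly-6D+ CpG replicate 1 (-0.07) or 2 (-0.05), and for cytokine receptors without Ly-6D+ PBS replicate 1 (0.05) or 2 (0.22). The other 15 lists did not pass, and among them the median and mean differed in sign for conventional dendritic cell (-0.02 and 0.11) and haematopoietic stem cell markers (0.03 and -0.01), both tested as upward. The lineage genes Ebf1 (-0.51), Pax5 (-0.39), Il7r (-0.03) and Tlr9 (-0.01) did not pass.

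In the Ly-6D+ comparison, the count of 6 ran between 4 and 16 when 1 array was left out, moving by more than 1.5 times without Ly-6D+ CpG replicate 3 (16), Ly-6D+ PBS replicate 2 (15) and Ly-6D- CpG replicate 3 (11). H2-Aa, H2-Ab1, H2-Eb1 and Gm4951 passed whichever array was left out, and the calls of Ehd3 and Muc13 each ended in 8 of the 11 cases, with adjusted p up to 0.242 without Ly-6D+ PBS replicate 1. The count was 0 when only the Ly-6D+ arrays were fitted (limma), 18 with a variance trend and robust estimation, and 16 without the arrays numbered 3, a setting chosen after their shared deviation was seen.

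**Figure D1:**
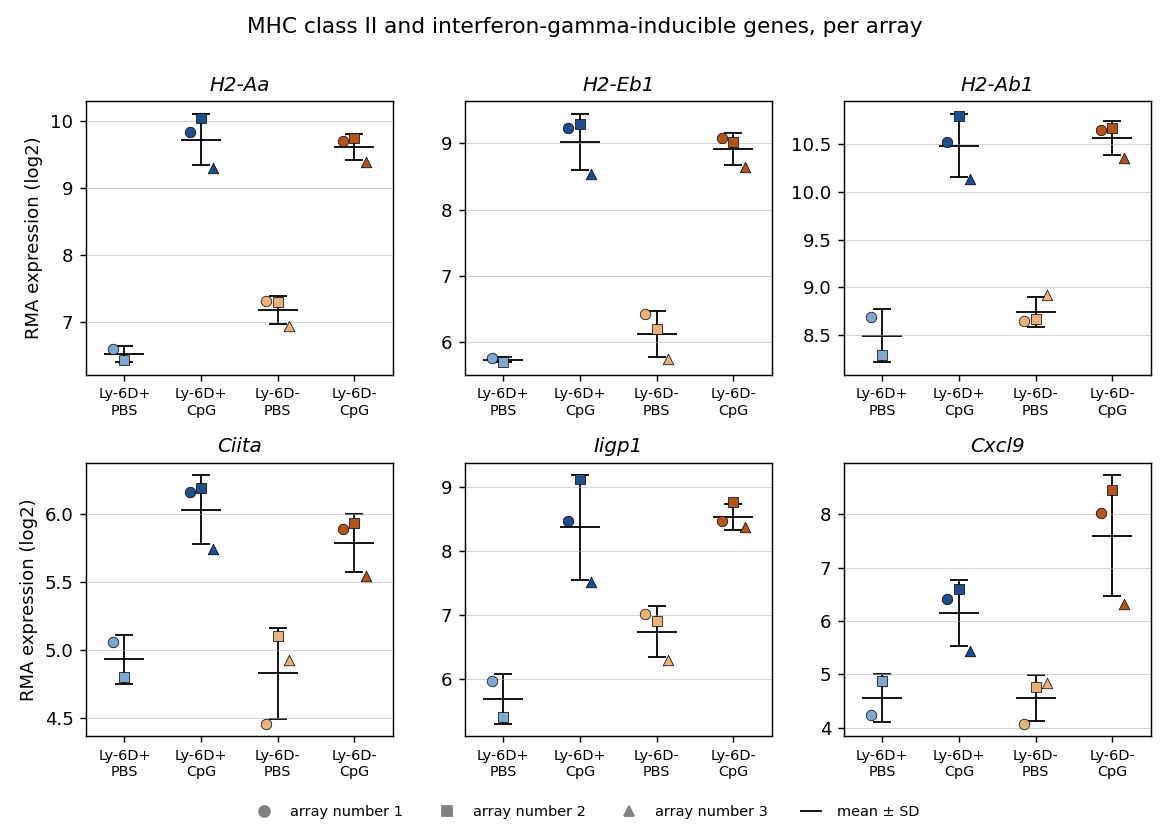
RMA expression (log2, vertical axes) of H2-Aa, H2-Eb1, H2-Ab1, Ciita, Iigp1 and Cxcl9 in the 4 groups; symbols are arrays by number and bars are the mean ± SD. H2-Eb1 lies between 5.71 and 6.43 in the PBS arrays and between 8.54 and 9.30 in the CpG arrays.

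The next question was the response of Ly-6D- CLPs, the population that had not taken on the B-lineage marker. MHC class II genes rose here as well, H2-Eb1 6.89-fold (SE 0.23 on the log2 scale, limma adjusted p = 0.00159), H2-Aa 5.37-fold (SE 0.19, adjusted p = 0.00159) and H2-Ab1 3.53-fold (SE 0.18, adjusted p = 0.00624), with 3 CpG and 3 PBS arrays. Cxcl9, a chemokine induced by interferon-gamma, rose 8.22-fold (SE 0.50, adjusted p = 0.0336), or 12.8-fold without Ly-6D- CpG replicate 3 (adjusted p = 0.00292). Its call ended without Ly-6D+ CpG replicate 1 (limma adjusted p = 0.0592) or 2 (0.0502), and also without Ly-6D- CpG replicate 2. Ifi30, a lysosomal thiol reductase of antigen processing, rose 4.69-fold (SE 0.24, adjusted p = 0.00660). Other rises were those of the coagulation factor subunit F13a1 (log2 change 1.81, SE 0.21, adjusted p = 0.0101), the cytokine receptor chain Csf2rb2 (3.25-fold, SE 0.21, adjusted p = 0.0108) and the chemokine receptor Ccr2 (2.97-fold, SE 0.19, adjusted p = 0.0101), of which Ccr2 alone is in the granulocyte and monocyte list. Il7r, the receptor for the cytokine IL-7 that lymphoid progenitors need, fell by 0.81 on the log2 scale (SE 0.13, adjusted p = 0.0300), and Rag2, of the antigen receptor recombinase, fell by 0.75 (SE 0.11, adjusted p = 0.0221).

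Among the further named rises were Tmem178 (log2 change 1.88), Pros1 (1.56), the metallothionein Mt1 (1.51), the chemokine Cxcl10 (2.83-fold), the transcription factor Klf4 (1.34), Igtp (1.03) and Nlrc5 (0.65), the transactivator of MHC class I genes. The 12 named falls ran from Bank1, a B-cell scaffold protein (-0.97), to Il17re (-1.38), and included the prostaglandin receptor Ptger2 (-1.01, SE 0.11, adjusted p = 0.00660), Gimap1 (-1.01, against 0.09 in its other probe set), Cd33 (-1.05), Postn (-1.25) and Tspan6 (-1.36). The limma test passed 121 genes, 67 higher and 54 lower, against 2664 with an unadjusted p under 0.05. The arrays of the 2 groups did not overlap for any of the 121, as for 15.7% of all genes, where chance gives 10%.

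Of the fixed lists in Ly-6D- CLPs, 12 passed the camera test, and 0 of these calls held with an estimated correlation. By fry, which does not compare a list with other genes, 2 of them did not pass. These were the interferon-stimulated genes (fry adjusted p = 0.180) and the granulocyte and monocyte markers (0.219), and the others passed (0.00684 to 0.0320). The highest lists were the interferon-gamma-inducible GTPases and chemokines (median 0.61, 3 of 15 measured members past the test, 8 when adjusted over the list alone, camera adjusted p = 1.85e-08) and MHC class II (median 0.48, 3 of 9 past, 4 higher and 1 lower when adjusted over the list alone, camera adjusted p = 6.28e-07), each with adjusted p = 0.0987 with an estimated correlation. Also upward were MHC class I (median 0.25, 1 of 15 rose, 4 when adjusted over the list alone) and the plasmacytoid dendritic cell markers (0.32, 3 of 14 rose and 1 fell, 6 and 5 when adjusted over the list alone), with adjusted p = 0.156 and 0.270 with an estimated correlation. The conventional dendritic cell markers (0.15, 0 of 11 passed, 4 higher and 1 lower when adjusted over the list alone) and the granulocyte and monocyte markers (0.19, 1 of 22 rose, 6 higher and 1 lower when adjusted over the list alone) had adjusted p = 0.0987 and 0.478 with an estimated correlation. Of the 17 G1/S (0.16) and 17 G2/M (0.24) cell cycle genes 0 passed, 2 and 3 when adjusted over the list alone, with adjusted p = 0.0987 and 0.156 with an estimated correlation. Downward were the early lymphoid progenitor genes (median -0.28, 2 of 15 fell, 7 when adjusted over the list alone, camera adjusted p = 7.53e-08), B-lineage specification (-0.29, 1 of 23 fell, 8 when adjusted over the list alone, camera adjusted p = 1.88e-05), the interferon-stimulated genes (-0.25, 1 of 29 fell, 2 when adjusted over the list alone) and the haematopoietic stem cell markers (-0.23, 0 of 15 passed, 4 when adjusted over the list alone). With an estimated correlation these had adjusted p = 0.0987, 0.0987, 0.347 and 0.156. Rag2 and Dntt are in both the early lymphoid progenitor and B-lineage lists, and Rag2 is counted among the falls past the test in both. The interferon-stimulated list lost its call without Ly-6D- PBS replicate 1 (median -0.10, adjusted p = 0.0598) and the granulocyte and monocyte list without Ly-6D- CpG replicate 1 (median 0.07, adjusted p = 0.0533). The plasmacytoid list lost it without Ly-6D+ CpG replicate 2, Ly-6D- CpG replicate 1 or 2, or Ly-6D- PBS replicate 3, with adjusted p up to 0.114. Other medians moved by more than 1.5 times as well. The granulocyte and monocyte median was 0.11 and 0.34 without Ly-6D- CpG replicates 2 and 3, and 0.12 without Ly-6D- PBS replicate 1 or 3. The B-lineage median was -0.15 without Ly-6D- CpG replicate 1 and -0.19 without Ly-6D- PBS replicate 3, an array without which those of MHC class I and G2/M genes were 0.15 and 0.09. The MHC class II median was 0.73 without Ly-6D- CpG replicate 3. In 2 lists that did not pass the median and mean differed in sign, erythroid and megakaryocyte markers (0.0015 and -0.17, tested as downward) and immediate-early and heat-shock genes (-0.07 and 0.14, tested as upward). Tlr9 (0.87, SE 0.19, adjusted p = 0.0760), Csf1r (1.08, adjusted p = 0.0524) and Ebf1 (-0.72, adjusted p = 0.112) did not pass.

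In the Ly-6D- comparison, the count of 121 ran between 5 (without Ly-6D- CpG replicate 2) and 309 (without Ly-6D- CpG replicate 3), and every array but Ly-6D+ CpG replicate 3 moved it by more than 1.5 times. It was 33, 69, 44 and 44 without Ly-6D+ CpG replicates 1 and 2 and Ly-6D+ PBS replicates 1 and 2, 12 without Ly-6D- CpG replicate 1, and 35, 22 and 14 without Ly-6D- PBS replicates 1, 2 and 3. Of the 35 genes drawn by the naming rule for this comparison that passed, H2-Aa, H2-Ab1, H2-Eb1 and Ptger2 passed whichever array was left out, and 31 calls ended without Ly-6D- CpG replicate 2. The number of calls ended was 20, 12 and 9 for Ly-6D+ CpG replicates 1, 2 and 3, and 19 for each Ly-6D+ PBS array. It was 26 and 1 for Ly-6D- CpG replicates 1 and 3, and 22, 24 and 27 for Ly-6D- PBS replicates 1, 2 and 3. On the second principal component Ly-6D- CpG replicates 2 and 1 lay at 19.4 and 22.7. The 3 Ly-6D- PBS arrays lay between -22.6 and -15.2, and Ly-6D- CpG replicate 3 at -0.74. The count was 4 when only the Ly-6D- arrays were fitted, 425 with a variance trend and robust estimation, 236 without the dimmest 33.3% of genes and 207 with array weights.

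**Figure D2:**
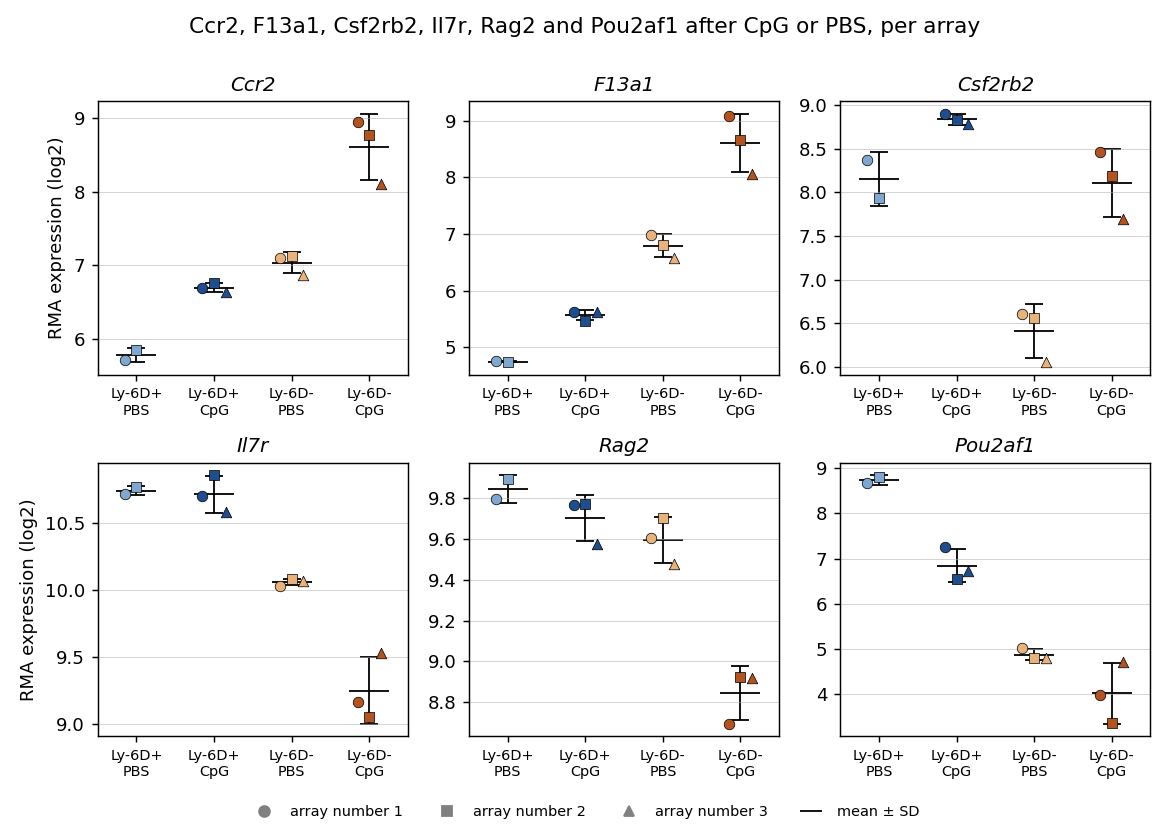
RMA expression (log2, vertical axes) of Ccr2, F13a1, Csf2rb2, Il7r, Rag2 and Pou2af1 in the 4 groups; symbols are arrays by number and bars are the mean ± SD. In Ly-6D- CLPs, Ccr2 lies between 6.87 and 7.13 after PBS and between 8.10 and 8.95 after CpG.

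Averaged over both populations, CpG raised Saa3, an acute-phase serum amyloid A protein, 10.8-fold (SE 0.60 on the log2 scale, limma adjusted p = 0.0443). H2-Eb1 rose 8.21-fold (SE 0.17, adjusted p = 3.72e-05), H2-Aa 7.03-fold (SE 0.14, adjusted p = 2.46e-05) and H2-Ab1 3.75-fold (SE 0.13, adjusted p = 1.74e-04). Cxcl9 rose 4.99-fold (SE 0.38, adjusted p = 0.0317), the immunity-related GTPase Iigp1 rose 4.71-fold (SE 0.26, adjusted p = 0.00853), and Ciita, which passed in this average, rose 2.04-fold (SE 0.14, adjusted p = 0.0167). The named falls were led by Pou2af1 (log2 change -1.37, SE 0.22, adjusted p = 0.0309), followed by Eya2 (-1.12), Tspan6 (-1.11), Pgr (-1.09), Vpreb3 (-1.06) and Wfdc18 (-1.04). Angpt1, which encodes the ligand angiopoietin-1, had a log2 change of -1.01 (SE 0.14, adjusted p = 0.0167). In all, 107 genes passed, 62 higher and 45 lower, and 2516 had an unadjusted p under 0.05.

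The interferon-gamma-inducible list rose in the average (median 0.76), with 5 of 15 measured members past the test, 12 when adjusted over the list alone, and adjusted p = 4.62e-17 by camera and 0.0431 with an estimated correlation. MHC class II rose (median 0.79), with 4 of 9 members past, 6 higher and 1 lower when adjusted over the list alone, and adjusted p = 1.22e-12 and 0.0431 with an estimated correlation. B-lineage specification fell (median -0.24), with Pou2af1, Vpreb3 and Rag2 the 3 of 23 members past, 9 when adjusted over the list alone, and adjusted p = 1.49e-10 and 0.0431 with an estimated correlation. These 3 lists also reached an exact stratified permutation p of 0.005, 2-sided, the smallest that 200 arrangements of the arrays allow (adjusted p = 0.0175 over 21 lists). That permutation test was added after the data were seen. It permuted treatment in each population separately. If the 2 populations come from the same animals, fewer arrangements are valid and its p values may be too small.

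The other lists that passed camera in the average lost the call with an estimated correlation. By fry, the MHC class I, G1/S, early lymphoid progenitor and conventional dendritic cell lists passed (fry adjusted p 0.00665 to 0.0400). The rest of these lists did not (0.149 to 0.235). MHC class I (median 0.20, 2 of 15 rose, 6 higher and 1 lower when adjusted over the list alone) had a camera adjusted p of 3.07e-07 and adjusted p = 0.141 with an estimated correlation. The G1/S genes (0.09, 0 of 17 past, 1 when adjusted over the list alone) had 7.52e-05 and adjusted p = 0.141 with an estimated correlation. Of the early lymphoid progenitor genes (median -0.13) 1 of 15 fell, Rag2, which the B-lineage list also holds. This early lymphoid list had 1 higher and 4 lower when adjusted over the list alone, and the same values were 8.30e-04 and 0.252. For the interferon-stimulated genes (-0.15, 0 of 29 past, 3 lower when adjusted over the list alone) they were 0.00652 and 0.427. The granulocyte and monocyte markers (0.06, 1 of 22 rose, 4 when adjusted over the list alone) had 0.0132 and 0.427, and the G2/M genes (0.07, 0 of 17 past, 0 when adjusted over the list alone) 0.0294 and 0.427. The conventional dendritic cell markers (0.06, 1 of 11 rose, 3 when adjusted over the list alone) had 0.0408 and 0.210, and the haematopoietic stem cell markers (-0.03, 1 of 15 fell, 1 when adjusted over the list alone) 0.0408 and 0.427. In the exact permutation test, MHC class I (adjusted p = 0.0300), G1/S genes and conventional dendritic cell markers (0.0175 each) passed and the other 5 of these 8 lists did not (0.173 to 0.392).

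Single arrays ended 5 of these calls. That of the interferon-stimulated genes ended without Ly-6D+ CpG replicate 3, Ly-6D+ PBS replicate 1 or Ly-6D- PBS replicate 1 (adjusted p up to 0.0779). That of the granulocyte and monocyte markers ended without Ly-6D+ CpG replicate 2, Ly-6D+ PBS replicate 1 or Ly-6D- CpG replicate 1 (up to 0.773). The G2/M call ended without Ly-6D+ CpG replicate 3, either Ly-6D+ PBS array, Ly-6D- CpG replicate 1 or Ly-6D- PBS replicate 3 (up to 0.325). The conventional dendritic cell call held without Ly-6D+ CpG replicate 1, Ly-6D+ PBS replicate 1, Ly-6D- CpG replicate 3 or Ly-6D- PBS replicate 1 and ended without any other array (up to 0.164). The stem cell call held without Ly-6D+ CpG replicate 2 or 3, Ly-6D- CpG replicate 3 or Ly-6D- PBS replicate 1 and ended without any other (up to 0.122). Several of these small medians moved by more than 1.5 times. The interferon-stimulated median was -0.07 without Ly-6D+ PBS replicate 1 or Ly-6D- PBS replicate 1, the G2/M median 0.02 without Ly-6D- PBS replicate 3, and the conventional dendritic cell median 0.04 without Ly-6D+ PBS replicate 2 or Ly-6D- CpG replicate 1. The granulocyte and monocyte median was 0.11, 0.0075 and 0.11 without Ly-6D+ CpG replicates 1, 2 and 3, and 0.01 and 0.23 without Ly-6D+ PBS replicates 1 and 2. It was 0.15 without Ly-6D- CpG replicate 3, and 0.01 and 0.15 without Ly-6D- PBS replicates 1 and 2. The stem cell median was -0.07 without Ly-6D+ CpG replicate 2, Ly-6D- CpG replicate 3 or Ly-6D- PBS replicate 3, -0.04 without Ly-6D- CpG replicate 1 or 2 or Ly-6D+ PBS replicate 1, and -0.11 without Ly-6D+ PBS replicate 2.

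The remaining lists did not pass camera in the average. Toll-like receptor signalling components (median 0.09) had adjusted p = 0.154, with 0 of 20 members past and 2 higher and 1 lower when adjusted over the list alone. NF-kB targets (0.01) had 0.424, with Bcl3 and Ccl5 risen and 3 higher and 2 lower when adjusted over the list alone, and passed the exact permutation test (adjusted p = 0.0175). T-cell markers (0.06) had 0.906, with 0 of 15 past and 1 lower when adjusted over the list alone. NK and innate lymphoid markers (0.01) had 0.221, with Il18r1 risen and 3 when adjusted over the list alone. Plasmacytoid dendritic cell markers (0.19) had 0.0696, with 0 of 14 past and 4 higher and 2 lower when adjusted over the list alone. Erythroid and megakaryocyte markers (0.03) had 0.937, with 0 past in either way. Mature B-cell and plasma-cell markers (-0.14) had 0.0768, with Ciita risen and Bank1 fallen and 2 each way when adjusted over the list alone. Apoptosis regulators (0.05) had 0.426, with 0 of 16 past and 2 higher and 1 lower when adjusted over the list alone. Cytokine receptors (0.08) had 0.104, with Il18r1 risen and 2 higher and 1 lower when adjusted over the list alone. Immediate-early and heat-shock genes (0.01) had 0.485, with Klf4 risen and Btg2 fallen and 3 higher and 1 lower when adjusted over the list alone. The mean of the erythroid and megakaryocyte list was -0.07, opposite in sign to its median and to the direction of its test.

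In the averaged comparison, the count of 107 ran between 6 (without Ly-6D+ PBS replicate 1) and 216 (without Ly-6D- CpG replicate 3), and every array but Ly-6D+ CpG replicate 3 moved it by more than 1.5 times. It was 28 and 41 without Ly-6D+ CpG replicates 1 and 2, 15 without Ly-6D+ PBS replicate 2, 28 and 30 without Ly-6D- CpG replicates 1 and 2, and 34, 46 and 51 without Ly-6D- PBS replicates 1, 2 and 3. Of 27 genes drawn by the naming rule that passed, H2-Aa, H2-Ab1 and H2-Eb1 passed whichever array was left out, and 23 calls ended without Ly-6D+ PBS replicate 1 and 23 without replicate 2. The number ended was 19, 15 and 8 for Ly-6D+ CpG replicates 1, 2 and 3, 17, 19 and 2 for Ly-6D- CpG replicates 1, 2 and 3, and 17, 14 and 12 for Ly-6D- PBS replicates 1, 2 and 3. With a variance trend and robust estimation the count was 302.

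**Figure D3:**
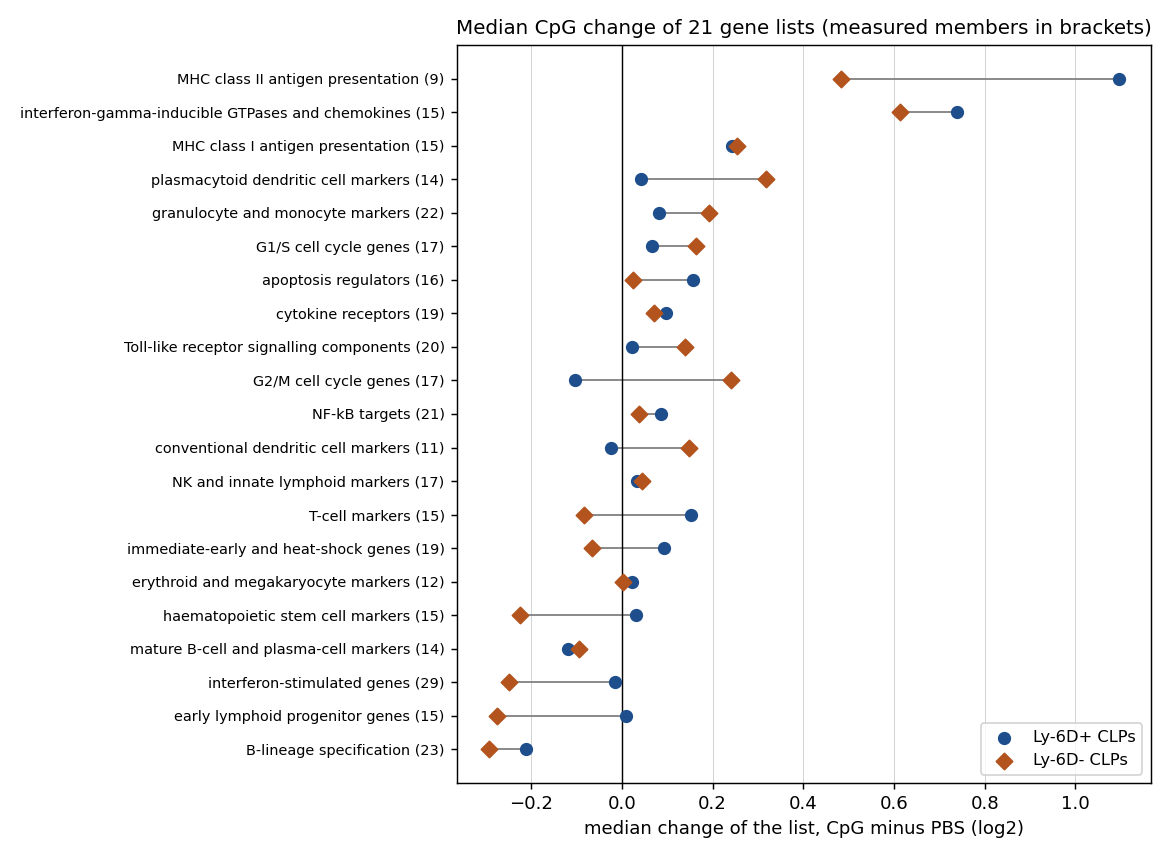
Median log2 change of each of the 21 fixed gene lists (vertical axis, number of measured members in brackets) after CpG, with circles for Ly-6D+ and diamonds for Ly-6D- CLPs. MHC class II has medians of 1.10 and 0.48, and B-lineage specification -0.21 and -0.29.

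Whether the populations responded differently was tested as the difference of their CpG effects. By limma, 0 genes passed (smallest adjusted p = 0.231), although 1413 had an unadjusted p under 0.05, and all other limma settings with every array gave 0 too. Without Ly-6D+ PBS replicate 1 the count was 1. The genes with the smallest p included the adaptor Dok3, with a difference of -1.28 (SE 0.16, adjusted p = 0.231), Gcnt2 (1.29), Sv2a (1.38), Rhobtb3 (1.19), Vldlr (1.08), Cd6 (1.04), Cldn12 (0.87), Defa-ps12 (-0.71), Gas7 (-1.04) and Klf4 (-1.29), and none of these passed. For Il7r, which fell in Ly-6D- CLPs, the difference was 0.78 (SE 0.19, adjusted p = 0.583), and for Tlr9 it was -0.88 (SE 0.28, adjusted p = 0.658). By camera, 5 lists differed, and none of these calls held with an estimated correlation. They were early lymphoid progenitor genes (median 0.31, camera adjusted p = 7.46e-08), MHC class II (0.41, 0.00492) and haematopoietic stem cell markers (0.40, 0.0172), which were higher in the Ly-6D+ response, and G2/M (-0.34, 1.20e-08) and G1/S genes (-0.12, 0.0315), which were lower. Their adjusted p values with an estimated correlation were 0.377, 0.423, 0.423, 0.377 and 0.423. By fry the adjusted p values were 0.0990, 0.286, 0.244, 0.124 and 0.244. No member of these lists passed over all genes, and 3, 0, 4, 0 and 0 did in that order when adjusted over the list alone. The MHC class II call also ended without Ly-6D+ CpG replicate 2 (0.0602) or Ly-6D+ PBS replicate 2 (0.0585). Both the stem cell and G1/S calls ended without Ly-6D+ CpG replicate 2 or 3, Ly-6D+ PBS replicate 2, Ly-6D- CpG replicate 1 or Ly-6D- PBS replicate 2. The G1/S call ended also without Ly-6D+ PBS replicate 1 or Ly-6D- CpG replicate 2 (0.0527 to 0.150 over both lists). The stem cell median was 0.22 without Ly-6D+ PBS replicate 2 and 0.21 without Ly-6D- CpG replicate 1, and the G2/M median -0.21 without Ly-6D- PBS replicate 3. In 4 lists that did not pass the median and mean differed in sign: MHC class I (0.02 and -0.04, tested as downward), NF-kB targets (-0.0054 and 0.013), NK and innate lymphoid markers (-0.07 and 0.04) and immediate-early and heat-shock genes (0.06 and -0.06), the last 3 tested as upward.

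The 2 CpG comparisons share no arrays, but they share the estimate of spread per gene, and the 2 populations may come from the same animals. Of the 121 genes that passed in Ly-6D- CLPs, 99 (81.8%) had the same sign in Ly-6D+ CLPs, against 55.3% of all genes. Their median absolute log2 change was 0.879 in Ly-6D- CLPs, and in that direction their median was 0.178 in Ly-6D+ CLPs. The genes were chosen by their Ly-6D- values, so the 2 medians are not a fair comparison of size. Among the genes that passed in both, 5 were higher in both, H2-Aa, H2-Ab1 and H2-Eb1 among them. Independent comparisons and genes would give 0.0181, so the excess is not a test. The correlation of the changes across all genes, which are not independent replicates, was r = 0.249.

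Ly-6D+ and Ly-6D- CLPs were compared in PBS-treated mice to give the difference between the populations without CpG. Ly-6D+ CLPs had higher levels of the pre-B-cell receptor genes Igll1, at 10.64 ± 0.06 (SD, n = 2) against 4.88 ± 0.08 (SD, n = 3), a 54.0-fold difference (SE 0.23 on the log2 scale, limma adjusted p = 1.68e-06), and Vpreb2, at 32.2-fold (SE 0.32, adjusted p = 1.72e-05). The B-cell receptor component Cd79a was 28.8-fold higher (SE 0.29, adjusted p = 1.40e-05), Ly6d 20.4-fold (SE 0.18, adjusted p = 1.68e-06), and the B-lineage transcription factors Ebf1 12.5-fold (SE 0.19, adjusted p = 9.24e-06) and Pax5 5.96-fold (SE 0.19, adjusted p = 5.08e-05). Gfra2, Spib, Pou2af1, Vpreb3, Cecr2, Lynx1 and Mzb1 were 9.23 to 22.4-fold higher. Tlr9, the receptor for CpG, was 3.03-fold higher in Ly-6D+ CLPs (SE 0.21, adjusted p = 0.00280). Lower in Ly-6D+ CLPs were Mc5r (log2 difference -3.23, SE 0.52, adjusted p = 0.00915), Rab38 (-3.17), the mast-cell protease Cpa3 (-2.94), Myct1 (-2.81), Emcn (-2.46), F13a1 (-2.05), the stem and progenitor antigen Cd34 (-1.50) and the receptor Kit (-1.08).

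Of 23 measured B-lineage specification genes, 15 were higher in Ly-6D+ CLPs, 19 when adjusted over the list alone, and the list passed (median 1.70, camera adjusted p = 1.17e-37, adjusted p = 7.30e-04 with an estimated correlation). The plasmacytoid dendritic cell markers were higher, with 9 of 14 past, 12 when adjusted over the list alone (median 0.94, camera adjusted p = 1.69e-20, adjusted p = 0.00243 with an estimated correlation), among them the lectin Siglech (6.80-fold) and Spib, which the B-lineage list also holds. The mature B-cell and plasma-cell markers were higher (median 0.31, 2 of 14 past, 6 when adjusted over the list alone, camera adjusted p = 1.50e-04, adjusted p = 0.0246 with an estimated correlation). The haematopoietic stem cell markers were lower by camera (median -0.77, 8 of 15 past, 9 lower and 1 higher when adjusted over the list alone, camera adjusted p = 4.41e-08, adjusted p = 0.0576 with an estimated correlation), with Cd34, Hlf, Gata2 and Meis1 among them. G1/S (median 0.20) and G2/M genes (0.37) were higher and the granulocyte and monocyte (-0.28), erythroid and megakaryocyte (-0.29) and cytokine receptor lists (-0.10) lower by camera. With an estimated correlation their adjusted p values were 0.0576, 0.0937, 0.254, 0.254 and 0.254. By fry these were 8.63e-04, 0.00525, 0.0619, 0.0317 and 0.0171, and that of the stem cell markers was 6.80e-04. Of the G1/S and G2/M genes 3 and 1 were higher past the test over all genes, 4 and 13 when adjusted over the list alone, and of the granulocyte and monocyte markers 3 were lower, 8 when adjusted over the list alone. The erythroid and megakaryocyte list had 1 higher and 2 lower in either way. The cytokine receptor list had 1 higher and 3 lower over all genes, 3 and 6 when adjusted over the list alone. The erythroid call also ended without Ly-6D+ PBS replicate 2 (0.137), Ly-6D- PBS replicate 2 (0.0968) or Ly-6D- PBS replicate 3 (0.0860), and the cytokine receptor call without Ly-6D- PBS replicate 1 (0.0869). The granulocyte and monocyte median was -0.11 and -0.69 without Ly-6D+ PBS replicates 1 and 2, the erythroid median -0.16 without Ly-6D+ PBS replicate 2, and the cytokine receptor median -0.05 without Ly-6D- PBS replicate 2. Lists that did not pass and whose median, mean and test differed in sign were the interferon-gamma-inducible list (-0.10 and 0.05, tested as downward), MHC class I (-0.03 and 0.07, upward), early lymphoid progenitor genes (-0.01 and -0.01, upward) and NK and innate lymphoid markers (0.05 and 0.06, downward).

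Between the populations after PBS, 439 genes passed, 262 higher and 177 lower in Ly-6D+ CLPs. The count ran between 185 and 416 with 1 array left out, moving by more than 1.5 times without Ly-6D+ PBS replicate 1 (185), Ly-6D+ PBS replicate 2 (213) and Ly-6D- PBS replicate 2 (285). By the limma test 2644 genes had an unadjusted p under 0.05. Of 54 genes drawn by the naming rule that passed, 38 passed whichever array was left out, Tlr9, Cd34 and Kit among them. The call of Mc5r ended without Ly-6D+ PBS replicate 1 (adjusted p = 0.0786) or 2 (0.0799), arrays that ended 14 and 11 of the calls, and each other array ended 2 to 7. The count was 190 when only the PBS arrays were fitted and 660 with a variance trend and robust estimation.

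**Figure D4:**
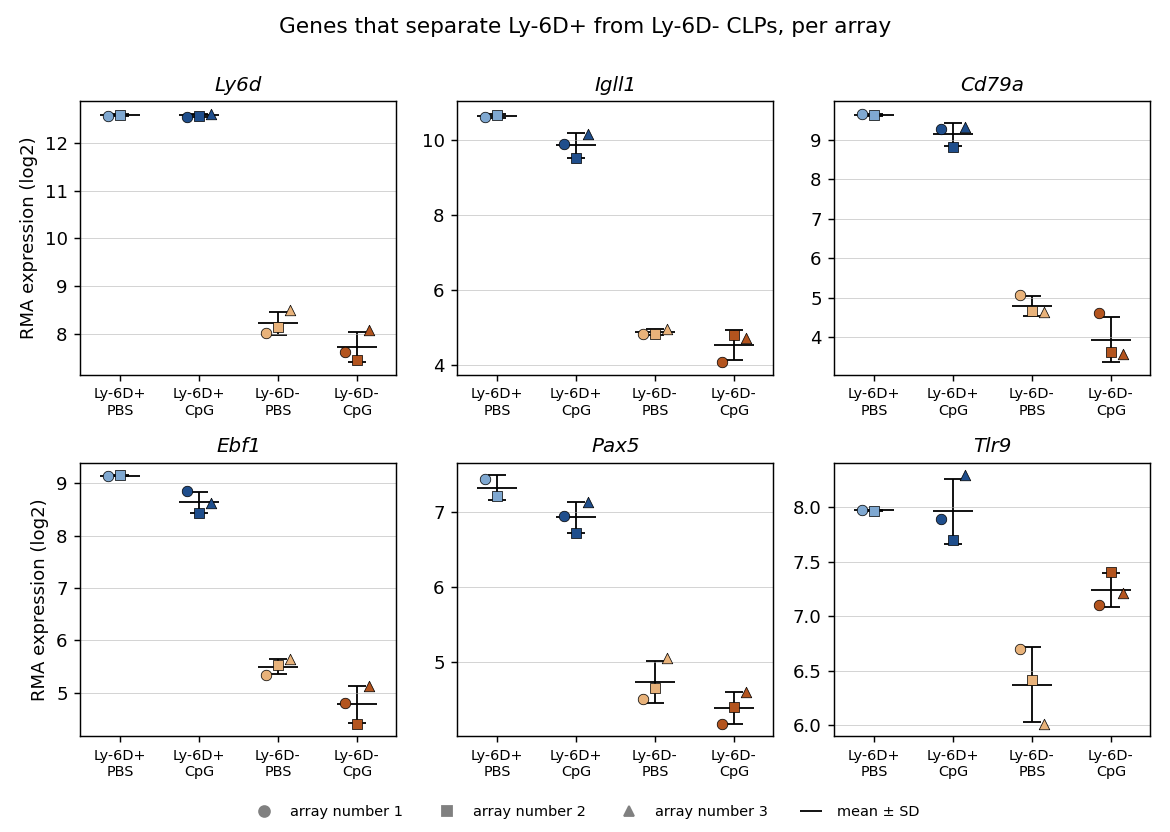
RMA expression (log2, vertical axes) of Ly6d, Igll1, Cd79a, Ebf1, Pax5 and Tlr9 in the 4 groups; symbols are arrays by number and bars are the mean ± SD. Ebf1 lies between 8.43 and 9.15 in the Ly-6D+ arrays and between 4.41 and 5.64 in the Ly-6D- arrays.

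The same comparison in CpG-treated mice gave the difference between the populations under treatment. Ly-6D+ CLPs were again higher in Igll1 (39.8-fold, SE 0.20 on the log2 scale, limma adjusted p = 4.93e-07, 3 arrays in each group), Cd79a (36.9-fold, SE 0.26), Ly6d (28.9-fold, SE 0.16), Vpreb2 (20.4-fold, SE 0.28), Ebf1 (14.4-fold, SE 0.17) and Pax5 (5.77-fold, SE 0.17). Il7r was 2.76-fold higher in Ly-6D+ CLPs (SE 0.13, adjusted p = 1.76e-04) and Rag2 1.81-fold (SE 0.11, adjusted p = 0.00157). Myct1 (log2 difference -3.41), F13a1 (-3.03), the chemokine Ccl9 (-2.65), Krt18 (-2.56), Rab38 (-2.53) and Anxa3 (-2.52) were lower. Ctsg (-2.36, SE 0.26), Ccr2 (-1.91, SE 0.19), Mpo (-1.78, SE 0.18) and Csf1r (-1.69, SE 0.21), all in the granulocyte and monocyte list, were lower as well. Tlr9 had a log2 difference of 0.72 (SE 0.19, adjusted p = 0.0945) and did not pass.

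Of 23 B-lineage specification genes, 17 were higher in Ly-6D+ CLPs after CpG, 19 when adjusted over the list alone (median 1.63, camera adjusted p = 1.42e-41, adjusted p = 5.26e-04 with an estimated correlation). The plasmacytoid dendritic cell markers were higher (median 0.69, 8 of 14 past, 11 when adjusted over the list alone, adjusted p = 0.00412 with an estimated correlation), as were the mature B-cell and plasma-cell markers (median 0.22, 2 of 14 past, 5 when adjusted over the list alone, adjusted p = 0.0268 with an estimated correlation). By camera the granulocyte and monocyte markers were lower (median -0.32, 7 of 22 past, 8 when adjusted over the list alone, camera adjusted p = 2.77e-08), a call lost at adjusted p = 0.217 with an estimated correlation. The early lymphoid progenitor genes (median 0.22, 3 of 15 past, 6 when adjusted over the list alone), T-cell markers (0.33, 1 of 15 past, 3 when adjusted over the list alone) and G1/S genes (0.09, 0 of 17 past, 0 when adjusted over the list alone) were higher by camera. The stem cell markers (-0.15, 5 of 15 past, 7 when adjusted over the list alone) and cytokine receptors (-0.19, 2 higher and 5 lower of 19, 3 and 6 when adjusted over the list alone) were lower. With an estimated correlation their adjusted p values were 0.130, 0.0543, 0.217, 0.130 and 0.367. By fry these were 0.00243, 0.00360, 0.0153, 0.00360 and 0.107, and that of the granulocyte and monocyte markers was 0.0154. The cytokine receptor call ended without Ly-6D+ CpG replicate 1 or 3, Ly-6D- CpG replicate 2 or 3, or Ly-6D- PBS replicate 1 or 2 (up to 0.125). Without Ly-6D- CpG replicate 2 the medians of cytokine receptors, T-cell markers and granulocyte and monocyte markers were -0.10, 0.16 and -0.21. Without Ly-6D+ CpG replicate 3 those of the granulocyte and monocyte and stem cell markers were -0.19 and -0.24, and without Ly-6D- CpG replicate 3 that of the stem cell markers was -0.09. Lists that did not pass and whose median, mean and test differed in sign were the interferon-stimulated genes (-0.04 and -0.02, tested as upward), MHC class I (-0.02 and 0.02, upward) and conventional dendritic cell markers (0.0060 and -0.09, downward).

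After CpG, 474 genes passed, 266 higher and 208 lower, and the count ran between 264 and 516 with 1 array left out. Of 37 genes drawn by the naming rule that passed, 31 passed whichever array was left out. The other 6 were Gbp8, Gbp9, Kit, Mecom, Tlr1 and Tlr7, and each array ended 0 to 5 calls. The count moved by more than 1.5 times without Ly-6D+ CpG replicate 1 (305), Ly-6D- CpG replicate 1 (295) and Ly-6D- CpG replicate 2 (264). It was 264 when only the CpG arrays were fitted, 726 with a variance trend and robust estimation, and 300 without the arrays numbered 3.

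The population comparisons after PBS and after CpG share no arrays, but they share the estimate of spread per gene. Between them, 138 genes were higher in Ly-6D+ CLPs in both, 85 were lower in both, and 0 passed in opposite directions. Independent comparisons and genes would give 3.14 higher and 1.66 lower, so the excess is not a test. Across all genes, which are not independent replicates, the differences had r = 0.536.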

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

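The tests of cell markers, of the interferon lists and of the array numbers were chosen after the results were seen, and the counts of other splits were planned. A list was picked out here where camera called a difference between the CpG effects of the populations. In the 9 measured MHC class II genes the median difference, Ly-6D+ minus Ly-6D-, was 0.412, in early lymphoid progenitor genes 0.309, and in haematopoietic stem cell markers 0.395 (0.222 without Ly-6D+ PBS replicate 2 and 0.208 without Ly-6D- CpG replicate 1). It was -0.120 in G1/S and -0.339 in G2/M cell cycle genes (-0.211 without Ly-6D- PBS replicate 3), and none of these calls held with an estimated correlation. Among probe sets without a single gene symbol, which no comparison used, 3 passed for CpG in Ly-6D+ CLPs, 12 for the average, 29 for the populations after PBS and 41 after CpG.

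The first pattern was the rise of H2-Aa, H2-Ab1 and H2-Eb1 with CpG in both populations. RNA from other antigen-presenting cells could give it. The sort for CLPs is meant to remove mature cells, but it is not used here as evidence against their RNA, since S100a8, S100a9 and Camp, genes known from neutrophils, lay at 12.49 to 12.71, 11.51 to 11.84 and 10.63 to 11.37 on the log2 scale over all 11 arrays. A set of markers counted against a cell type where its median change plus 1 SD stayed below 0.5. Mature B cells met this bound, with median changes of their mid-level markers of -0.346 in Ly-6D- CLPs (SD 0.636, 7 markers) and -0.343 in Ly-6D+ CLPs (SD 0.292, 6 markers). The class II genes had median rises of 2.43 and 3.20. The 7 markers in Ly-6D- CLPs went both ways, from -0.97 for Bank1 to 0.83 for Cd22 (SE 0.17, adjusted p = 0.0596), and the median plus 1 SD was 0.289. Blk and Pax5, used in both populations, are also in the B-lineage list, whose fall with CpG could hide added B-cell RNA. Ms4a1, Fcer2a and Cr2 lay below the level used and did not pass, at -0.08, 0.23 and 0.18 in Ly-6D- CLPs. In Ly-6D+ CLPs they had -0.60, 0.13 and -0.32. This test therefore does not exclude mature B cells. Dendritic cells and monocytes cannot be told apart from a change within CLPs, because their markers had medians of 0.721 (SD 0.596) in Ly-6D- and 0.229 (SD 0.339) in Ly-6D+ CLPs (8 markers each), which reach 1.32 and 0.568 with 1 SD added. A CpG response within the CLPs therefore stays open beside RNA of these cell types, as a hypothesis.

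The next pattern was the rise of interferon-gamma-inducible genes. On average, the mean of that list minus the mean of the interferon-stimulated list rose by 0.967 with CpG (exact stratified permutation, 2-sided p = 0.005, the smallest that 200 arrangements allow). This is consistent with a response to interferon-gamma rather than to type I interferon, a hypothesis found and tested on the same data. If the 2 populations come from the same animals, fewer arrangements are valid and that permutation p may be too small. Chemokines in the interferon-gamma list may also come from other cells in the sort, which the tests above do not exclude.

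The last pattern was Ccr2, F13a1 and Csf2rb2 rising and Il7r falling in Ly-6D- CLPs. Granulocyte-monocyte progenitors could bring such transcripts, although the CLP gate is meant to remove them. Their 7 mid-level markers had a median change of 0.225 (SD 0.569), against 1.70 for the 3 genes that rose. Their abundant genes went apart, with Mpo at 0.16 and Elane at -0.29 but Prtn3 at 1.04, Ctsg at 1.09 and Ly6c2 at 1.09. Of these abundant genes only Ly6c2 passed (limma adjusted p = 0.0300). The 7 mid-level markers went both ways, from -0.58 for Csf3r to 1.28 for Ms4a6c. Their median plus 1 SD was 0.794, above the same bound of 0.5, so such cells cannot be told apart from a shift within the Ly-6D- CLPs.

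Other splits of the same arrays were counted for 3 comparisons. For CpG in Ly-6D- CLPs, 10 splits are too few for a share under 0.05; the real split, 1 of the 10, called 121 genes and the highest other 0. For the average, 1 of 100 splits, the real one, called as many as 107 genes, and the highest other called 1. The splits were drawn from 200 arrangements and permuted treatment in each population separately. If arrays of a number share an animal, fewer arrangements are valid. Splits that mix the treatments also put any CpG effect into the spread, which lowers their counts, so chance is not excluded. For the populations after CpG, 10 splits are again too few; the real split, 1 of the 10, called 474 and the highest other 0.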

How the results depend on the processing

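Leaving out the arrays numbered 3 and the exact permutation of list means were added after the data were seen, and the other settings were planned. No call of a named gene or list reversed its direction under the settings run for it; testing every probe set by itself was run for the counts only. Some genes that passed had a further probe set of opposite sign: 1 of 4 with several probe sets for CpG in Ly-6D- CLPs, 1 of 7 for the average, 3 of 27 for the populations after PBS and 4 of 37 after CpG. None of these opposite probe sets passed. Gimap1 was the 1 in both CpG comparisons, and its other probe set had 0.09 in Ly-6D- CLPs and 0.05 in the average. In the order CpG in Ly-6D+ CLPs, CpG in Ly-6D- CLPs, the average, populations after PBS and populations after CpG, the counts were 10, 326, 237, 697 and 727 at an adjusted p below 0.10, and 18, 425, 302, 660 and 726 with a variance trend and robust estimation. With only the groups compared in the fit, fewer arrays share the estimate of spread. The counts were then 0, 4, 190 and 264 for the comparisons other than the average and the difference, where this is the same fit. For CpG in Ly-6D- CLPs the count was 236 without the dimmest 33.3% of genes, where fewer genes were tested, and 207 with array weights. With the replicate number as a block it was 11 for CpG in Ly-6D+ CLPs and 108, 144, 0, 347 and 458 for the other comparisons, and with number within treatment as a block 207 after PBS, 361 after CpG and 0 for the difference. With the number as a block, 74 of the 108 and 85 of the 144 were also called in the main fit. That block lost 19 of 159 named calls and gained 8, and number within treatment lost 12 of 91. Without the arrays numbered 3 the counts were 16 for CpG in Ly-6D+ CLPs and 300 for the populations after CpG. With 1 array left out, the counts ran from 4 to 16, 5 to 309, 6 to 216, 185 to 416 and 264 to 516, and from 0 to 1 for the difference. The cause of these changes in count was not tested. Of 159 named values that passed, 97 of 1334 values under other settings no longer passed, 53 of them with only the groups compared, and 486 of 1749 with 1 array left out; 42 and 19 values newly passed. Of 52 list calls, 76 of 323 values were lost under other settings and 68 of 572 with 1 array left out. Signal over background is unknown without detection values, so dim genes were kept.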

Other observations

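The tests of the array numbers were chosen after their deviation was seen. The arrays with the number 3 departed from their group means together, with residual correlations of 0.0905 to 0.176 across genes, against -0.127 to 0.0912 for arrays of different numbers. Residuals cancel within a group, so high correlations of same-numbered arrays lower those of different numbers. The ranges compared here and below are therefore not independent. In both CpG groups the array numbered 3 had the lowest H2-Eb1, Cxcl9 and Saa3, with Saa3 at 5.76 in Ly-6D+ CLPs, against 8.73 and 9.05 in the other two. A day, animal or handling step shared by arrays of a number may contribute, but was not tested apart from that deviation. The mean residual correlation of same-numbered arrays was 0.0484 (exact 1-sided p = 0.0463 over 432 assignments of numbers), which includes the correlations in which the deviation was seen and so only restates it. Lower quality of these arrays cannot be told apart from such a step, since the spread (interquartile range) of relative log values was 0.183 in the tightest of the 3 and 0.210 and 0.218 in the other two, on both sides of the median of 0.194 in the other arrays. The main fit did not pair the arrays by number, and whether the numbers pair them is not settled. Residual correlations were -0.0345 to 0.0584 for arrays numbered 1 and 0.00721 to 0.0961 for those numbered 2. The highest residual correlation was with an array of the same number for 8 arrays. Between the populations after CpG, same-numbered pairs had 0.0584, 0.0961 and 0.176, against -0.127 to 0.0386 for different numbers. After PBS such pairs had -0.0065 and 0.0275, against -0.0324 to 0.0324. The residuals of the 2 Ly-6D+ PBS arrays are mirror images, so that last range is symmetric by construction.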
